A study of Drosophila melanogaster with 66 samples.

How the data were processed

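The series holds 66 samples of sexed Drosophila melanogaster embryos, made with meiotic drive crosses that give offspring of 1 sex and sorted by hand by nuclear cycle, per the labels. At nuclear cycles 11 to 14, 200 embryos were pooled per sample, and a further stage is given as 2-4 h. Samples were grouped by sex, stage and antibody from their labels. Bowtie2, Picard, SAMtools 1.9 and MACS2 2.1.1 and the genome build dm6 are named in the submitters' processing notes, without order or settings; which control library was used, and whether replicates were pooled before peaks were called, is not given in the sources used here.

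CLAMP files are narrow peak lists and H4K16ac and MSL3 files are broad peak lists. The fold enrichment of each peak over the local background is a ratio that the authors' peak caller gave, and it has no scaling between lists. The −log10 p and −log10 q of each peak were also deposited by the authors; the lowest −log10 q was 2.003 in the narrow lists and 1.301 in the broad ones. The score column deposited for each peak was tested on the files and is the whole part of 10 times −log10 q. The summit offset in the narrow lists, deposited in base pairs from the start of the region, was not used, since several summits can share a region. Each region was therefore counted once, with the highest fold and −log10 q of its summits. These values were used to rank or filter regions within a list and, at regions found in both sexes, as medians on X relative to the autosomes of the same list.

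There was 1 list for each sex, stage and antibody, and 9 groups have 2 labelled replicates but 1 list, so no spread between replicates could be measured. The list is filed under replicate 2 for male cycle 12 MSL3, male cycle 13 MSL3 and male cycle 13 CLAMP, and under replicate 1 for the others. Differences of these lists from others cannot be told apart from a difference between replicates. The IgG and input samples and the unlisted replicates were not analysed here. Read depth was unknown. Regions on chromosomes 4, Y and the mitochondrial genome were left out of ratios, because chromosome 4 is small and heterochromatic and the other 2 are not autosome arms.

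Gene positions came from the RefSeq table of Release 6 (dm6), with 17807 genes. It gives no strand and no exons, so the planned 1 kb upstream of a gene became 1 kb on either side, and a gene was called occupied when a region overlapped it or that flank. Arm lengths were taken as the end of the last annotated gene, 23.54 Mb for X and 108.8 Mb for 2L, 2R, 3L and 3R together. The share of GA motifs under CLAMP summits was planned and not run, since no genome sequence was used here.

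The X to autosome ratio is regions per Mb on X over regions per Mb on the 4 arms, with 0.5 added to each count. Its 95% interval came from 10000 bootstrap resamples of 136 blocks of 1 Mb (24 on X), and its p from 100000 permutations of the X and autosome labels over blocks, two-sided, adjusted by Benjamini-Hochberg over 25 lists. The male minus female difference of log2 ratios used the same blocks in both lists and was adjusted over 10 comparisons, and the mean over the 5 stages was tested with an exact sign-flip test, two-sided and adjusted over 2 antibodies. Overlap was at least 1 bp, compared with 1000 circular shifts of 1 list along each arm by at least 100 kb, adjusted within a family of comparisons; the smallest p these give is 0.000999. Shares of regions have exact Clopper-Pearson 95% intervals.

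Genes are named by a rule fixed before the data were examined, as were the gene lists, the tests of the comparisons and most alternatives, but not most tests of technical explanations. It takes the roX and MSL complex genes and the histone gene cluster always; up to 4 examples of highest fold per list; up to 8 X-linked and 3 autosomal genes at the MSL3 regions of highest fold at each stage; up to 8 genes at the strongest male 2-4 h CLAMP regions found in every CLAMP list; up to 8 genes with CLAMP in at least 3 lists of 1 sex and none of the other; and up to 8 X genes with H4K16ac over at least 50% of the body in males and under 10% in females at 2-4 h, longest first, with up to 4 the other way. For each of 15 gene lists the count of occupied genes was set against 10000 random lists of the same size. These were matched on deciles of gene length. The comparison describes these libraries and is not a test of replicates. Random genes were of any type, noncoding ones included, so percentiles may partly reflect coding against noncoding genes. The match is not on chromosome, so the percentile of the X-linked list would reflect its chromosome and is not given. That list enters only the counts of lists at or above percentile 95. Percentiles of other lists with members on X may partly reflect chromosome too. Among these are the MSL complex and roX genes (3 of 8 on X) and sex determination genes (5 of 16). The lists are the MSL complex and roX genes, pioneer and GA-binding factors, sex determination, first-wave zygotic, gap, pair-rule, dorsoventral and Hox genes, X-linked metabolic and housekeeping genes, autosomal housekeeping genes, ribosomal protein genes, replication-dependent histone genes, histone locus body genes, late differentiation genes as markers of older embryos, and maternal germline and follicle genes. All but 2 names, RpII215 and nos, were matched to 1 gene.

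Alternatives were regions with −log10 q of at least 5, the 300 regions of highest −log10 q, regions within 1 kb merged, base pairs in place of regions, chromosome 4 among the autosomes, blocks of 250 kb, 50% of a region to be covered, and each stage left out. X without its part beyond 22 Mb, blocks with at least 50 genes, every summit counted, gene bodies without flanks, and leaving out single lists were added after the data were seen.

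The tests were run on simulated lists with known answers. With no difference, the ratio of a list passed at 5% in 10% of simulations of 600 regions and 7% of 6000 regions. The male to female difference passed in 8 and 7%, so these p were slightly too small in the simulations. Blocks were simulated independently, so clusters of regions across blocks and lists shorter than 600 regions were not covered. Intervals held the true value in 88 to 98% of simulations. A male to female difference of −0.5 on the log2 scale was called in 62% of simulations with 600 regions and in 100% with 6000. Planted overlaps of 0, 20 and 80% were recovered as −0.100, 20.1 and 78.7% above shifts. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9.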

Results

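Chromatin immunoprecipitation followed by sequencing was used to map 3 targets in sexed Drosophila melanogaster embryos. CLAMP is a zinc finger protein that binds GA-rich DNA, and MSL3 is a chromodomain subunit of the male-specific lethal (MSL) dosage compensation complex. H4K16ac is acetylation of histone H4 at lysine 16, a mark that this complex deposits. The stages were nuclear cycles 11, 12, 13 and 14, the last syncytial divisions and the cycle in which the embryo cellularises, and embryos aged 2 to 4 h. Of 66 samples, 16 were CLAMP, 10 H4K16ac, 8 MSL3 (males only), 16 IgG and 16 input. Regions were analysed from 25 peak lists, 10 for CLAMP, 10 for H4K16ac and 5 for MSL3. There was 1 list per sex, stage and target, so no value here has a replicate error and every permutation p describes the listed libraries. The CLAMP lists held between 133 and 10466 regions, the H4K16ac lists between 1201 and 8087, and the MSL3 lists between 33 and 15149. Read depth was unknown, and intervals cover the spread along the genome or counting error only. Chromosome Y held 0, 0, 0, 8 and 16 regions in the male CLAMP lists in stage order and 5, 4, 3, 3 and 9 in the male H4K16ac lists. It held 0, 0, 0, 0 and 3 in the female CLAMP lists and 5, 1, 0, 0 and 2 in the female H4K16ac lists, so male counts were as high as female ones or higher, with 5 in both for H4K16ac at cycle 11.

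The first comparison asked when MSL3 is found on the male X. At cycle 14 the strongest X regions lay over IntS2, an Integrator subunit (X 17652612 to 17656749, fold enrichment 5.61), dlg1, a septate junction scaffold (5.48), the kinase gene Raf (5.16), ebo (4.92), dtn (4.91), boi, a Hedgehog co-receptor (4.83), PGRP-LE, a peptidoglycan sensor (4.79), and sno (4.70). The list held 590 regions on X and 827 on the autosome arms. The X regions had a median width of 3049 bp against 762 bp, and 184 of them were wider than 5 kb against 21 on the autosome arms. Among protein-coding genes, 50.6% on X and 9.56% on the autosome arms had MSL3 within 1 kb at cycle 14. The autosomal regions of highest fold at that stage lay over Alh (3.09), Bruce (2.59) and Gpdh3 (2.51), all on 3R.

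At cycle 12 the list held 33 regions, 30 of them on X, 1 on the autosome arms and 2 on the mitochondrial genome. The X regions of highest fold lay over Tango10 (X 11723091 to 11723332, fold 3.67), su(w[a]), a splicing regulator (3.54), PhKgamma, a phosphorylase kinase subunit (3.53), raptor, a subunit of the TORC1 kinase complex (3.49), CG4645 (3.46), dtn (3.45), dlg1 (3.42) and IntS2 (3.37). The autosomal one lay over gpp, the H3K79 methyltransferase gene (3R 6416605 to 6416895, 3.66). Of the 30 X regions, 13 lay before 22 Mb and 17 beyond it, at the end of the arm that carries the ribosomal RNA genes. Regions of the cycle 14 list overlapped all 13 of the former. At cycle 11 the X held 19 regions, 18 of them beyond 22 Mb. These included 28SrRNA-Psi:CR45859 (2.89) and 18SrRNA-Psi:CR41602 (2.82), and lncRNA:CR45668 (4.18) was the exception. The strongest autosomal regions lay over gpp (7.86), ctrip (6.67) and Lasp (5.36). At cycle 13 the strongest X regions lay over nocte (X 10464322 to 10472869, 4.89), CG2186 (4.76), roX1 (4.73), Tango4 (4.66), IntS2 (4.62), CG12236 (4.60), CG32537 (4.57) and sta, a ribosomal protein gene (4.55), beside gpp (5.88), ctrip (4.56) and sbb (4.51) on the autosomes. At 2-4 h the 6 X regions of highest fold lay beyond 22 Mb, led by a region at X 23253270 to 23253746 (26.8), and were followed by Dop2R, a dopamine receptor gene (6.15), and Or2a, an odorant receptor gene (5.35). On the autosomes scrib, a cell polarity gene (6.06), CenG1A (6.06) and 18w, the nearest gene to its region (5.91), led.

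The share of MSL3 regions on X was 50% at cycle 11 (exact 95% interval 33.4 to 66.6), 96.8% at cycle 12 (83.3 to 99.9), 12.8% at cycle 13 (12.2 to 13.3), 41.6% at cycle 14 (39.1 to 44.3) and 60.9% at 2-4 h (56.2 to 65.4). Per Mb, the X to autosome density ratio was 4.62 at cycle 11 (95% block bootstrap 0.130 to 16, adjusted permutation p = 0.228) and 93.9 at cycle 12 (19.1 to 522, p = 6.25e-05). It was 0.677 at cycle 13 (0.581 to 0.784, adjusted permutation p = 0.001), 3.30 at cycle 14 (2.63 to 4.08, p = 6.25e-05) and 7.18 at 2-4 h (5.59 to 9.05, p = 6.25e-05), where 6.25e-05 comes from the smallest p that 100000 permutations can give. Counted in base pairs the ratio was 340 at cycle 12 (adjusted permutation p = 0.135), 0.839 at cycle 13 (0.180), neither past the threshold, 11.6 at cycle 14 and 15.8 at 2-4 h. Of the cycle 13 regions, 1930 lay on X and 13183 on the autosome arms. Among those with −log10 q of at least 5 the share on X was 38.1% and the density ratio 2.85, the opposite direction. Without X beyond 22 Mb, the cycle 11 share was 5% and its ratio 0.380. The cycle 12 ratio also rests in part on that end, which holds 17 of the 30 X regions.

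**Figure D1:**
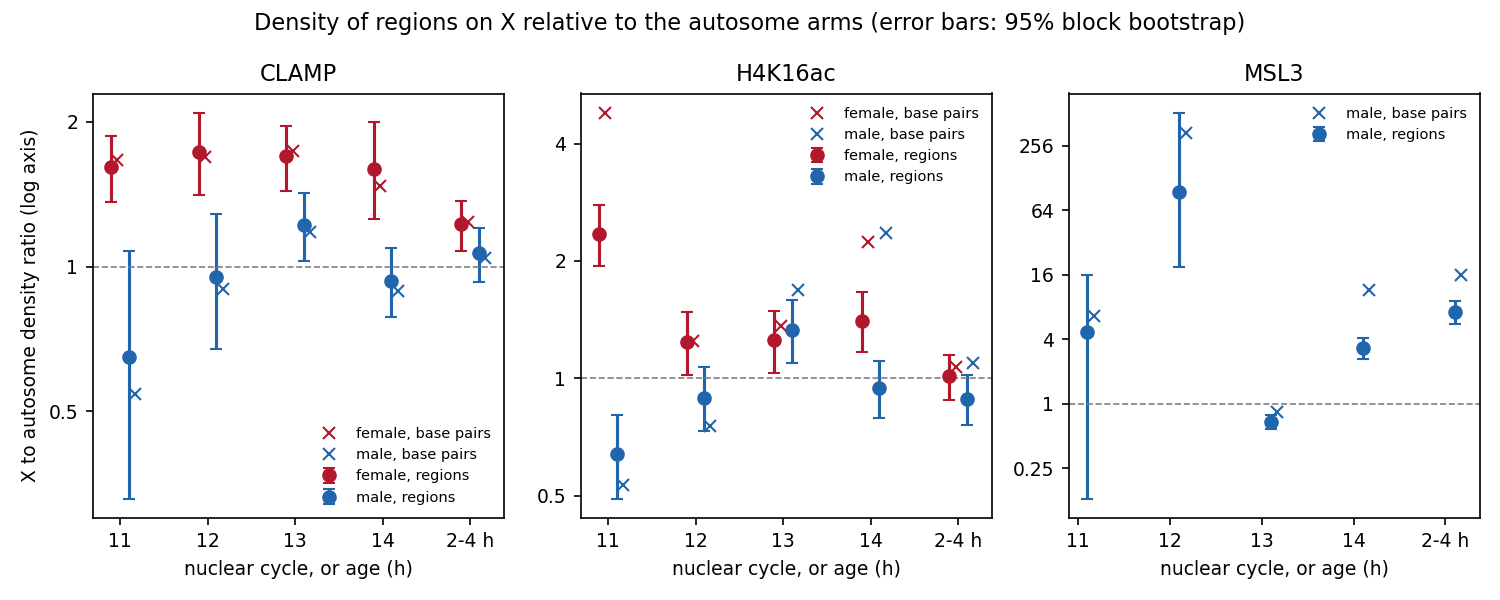
Ratio of regions per Mb on X to regions per Mb on the autosome arms (log axis) against stage for CLAMP, H4K16ac and MSL3, with circles for regions, error bars for the 95% block bootstrap interval and crosses for base pairs; females are red and males blue. The 5 female CLAMP ratios lie between 1.22 and 1.73 and the male ones between 0.649 and 1.22, and the MSL3 ratios in stage order are 4.62, 93.9, 0.677, 3.30 and 7.18.

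The second comparison set MSL3 beside H4K16ac and CLAMP in males of the same stage. At cycle 14, male H4K16ac regions overlapped 569 of the 590 X regions of MSL3 (96.4%, against 29.5% for shifted positions) and 40.5% of its autosomal ones (13.5% shifted). At 2-4 h they overlapped 73.6% of the X regions (15.1% shifted), at cycle 13 50.4% (14.7% shifted), at cycle 12 20% (4.81% shifted) and at cycle 11 31.6% (0.789% shifted). CLAMP overlapped 0% of the X regions of MSL3 at cycle 11, 10% at cycle 12, 5.96% at cycle 13, 23.9% at cycle 14 and 51.4% at 2-4 h, where shifted positions gave 0.0526, 0.447, 6.36, 19.7 and 11.6%. The highest value for CLAMP was on the autosome arms at 2-4 h, where it overlapped 148 of 180 MSL3 regions (82.2%, 7.49% shifted). Over X to 22 Mb, male H4K16ac covered 0.659% of the base pairs of the 568 cycle 14 MSL3 regions at cycle 11, 8.27% at cycle 12, 31.4% at cycle 13, 92.5% at cycle 14 (95% block bootstrap 91.0 to 93.9) and 38.5% at 2-4 h. Female H4K16ac covered 76.3, 17.9, 27.6, 57.9 and 17.2% of the same base pairs, and of the rest of X it covered 8.86% at cycle 11.

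The overlaps with H4K16ac on X passed at every stage (adjusted permutation p = 0.00143 at cycles 11, 13 and 14 and at 2-4 h, from the smallest p that 1000 shifts can give, and 0.00874 at cycle 12). Those on the autosome arms passed at cycles 13 and 14 and at 2-4 h (adjusted permutation p = 0.00143). They were 31.85% at cycle 13 (9.26% shifted) and 51.67% at 2-4 h (11.65% shifted). Relative to shifted positions, the autosomal overlap was 3.44, 3.00 and 4.43 times at these stages, beside 3.42, 3.27 and 4.88 times on X. The excess at these stages was therefore not particular to X. At cycle 12 the X regions of MSL3 that H4K16ac overlapped were 6 of the 17 beyond 22 Mb and 0 of the 13 before it, and those that CLAMP overlapped were 3 and 0. At cycle 11, 18 of the 19 X regions lie beyond 22 Mb, so the early overlaps rest mostly on the repeat-rich end of the arm. With CLAMP on X the adjusted permutation p was 1 at cycle 11, 0.002 at cycle 12, 0.702 at cycle 13, 0.015 at cycle 14 and 0.002 at 2-4 h. Of the regions in the male cycle 14 CLAMP list, 23.9% were found at male 2-4 h, and among regions with −log10 q of at least 5 the cycle 14 overlap with CLAMP no longer passed, on X (29.3%) or on the autosome arms (50%). With 50% of the region to be covered, the cycle 12 overlap on X was 0% with CLAMP and 10% with H4K16ac, and neither passed.

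**Figure D2:**
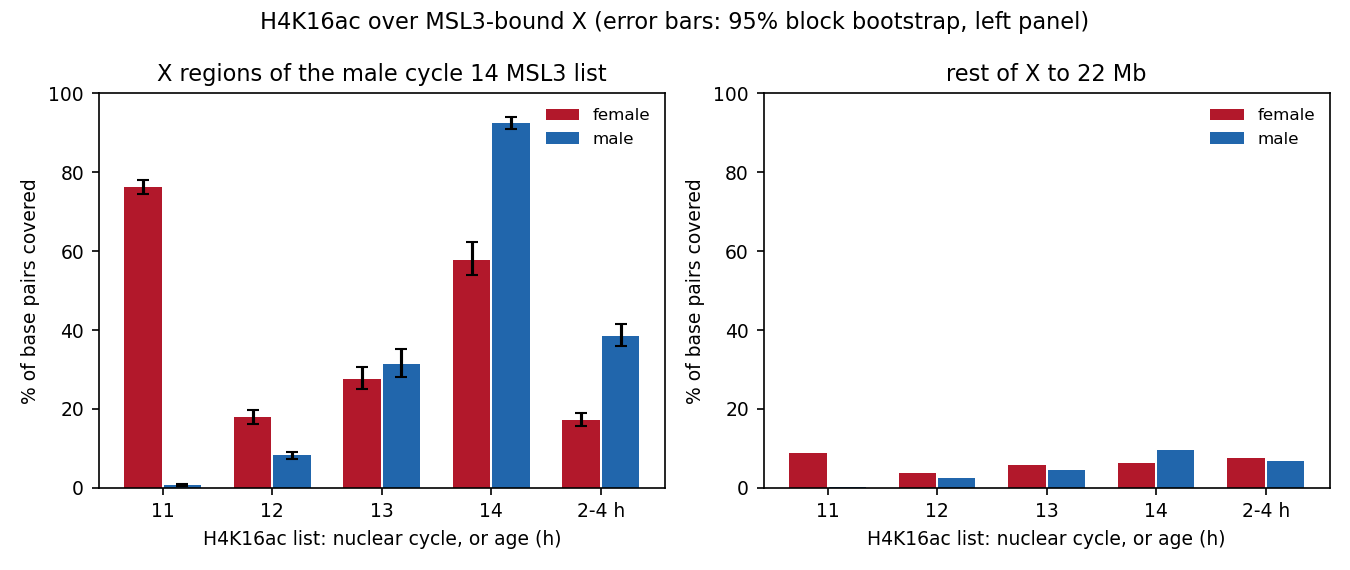
Percent of base pairs covered by each H4K16ac list, by stage and sex, in the X regions of the male cycle 14 MSL3 list (left, error bars 95% block bootstrap) and in the rest of X to 22 Mb (right). Male cover of the MSL3 regions is 92.5% at cycle 14, and female cover is 76.3% at cycle 11 and 57.9% at cycle 14.

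The third comparison asked where CLAMP is found, on X and the autosomes, in each sex. In females CLAMP regions were denser on X than on the autosome arms at all 5 stages, and in males at no stage past the threshold. In the male 2-4 h list, 57 regions were overlapped by regions of all 10 CLAMP lists, 6 of them on X. Those of highest fold lay over Rexo5 (3L 6605785 to 6606376, fold 29.7), Ptx1, a homeobox gene (25.4), CG1354 on X (25), the posterior patterning gene cad (24.4) and not, which encodes the ubiquitin protease of the SAGA complex (23.4), or nearest to Prat2, a purine synthesis gene (27.1), lncRNA:CR43302 (26.6) and lncRNA:CR45297 (23.3). Of the 500 strongest male 2-4 h regions, female lists overlapped 97.8% at cycle 11, 87.4% at cycle 12, 98.4% at cycle 13, 46.8% at cycle 14 and 100% at 2-4 h. Male lists overlapped 10.2, 62.4, 97.8 and 91.2% at cycles 11 to 14. The male cycle 11 list has 133 regions, which limits its share, and the female cycle 14 list has 523 on the arms.

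Few genes met the rule for restriction to 1 sex, which the rule and the list lengths favour. The male lists of cycles 11 and 12 had 133 and 604 regions. The 2-4 h lists alone had CLAMP at 66.8% of protein-coding X genes and 59.6% of autosomal ones in females. In males these shares were 62.4 and 58.9%. No count for comparison was computed, so the low counts are not a measure of how alike the sexes are. Tmtc1 on 2L had CLAMP in 3 male lists and no female list (fold 3.40 at male 2-4 h), and CG34435 on X had it in 3 female lists and no male list (2.90 at female 2-4 h). Without the male cycle 14 list, which stands apart from the others, these counts were 0 and 2. Most regions of the shorter list were shared at each stage. Female regions overlapped 61.7% of the 133 male regions at cycle 11, 93.8% of 599 at cycle 12, 68.6% of 4898 at cycle 13 and 92.2% of 10276 at 2-4 h, against 3.02, 0.877, 2.36 and 9.39% for shifted positions. Male regions overlapped 88.1% of the female ones at cycle 13. At cycle 14 the female list had 523 regions on the arms and overlapped 4.43% of 8377 male regions, and the male list overlapped 71.1% of the female ones. All of these exceeded shifted positions (adjusted permutation p = 0.000999, the smallest that 1000 shifts can give). Of the male cycle 14 regions, 23.9% were found in the male 2-4 h list, where for the other CLAMP lists the share was between 80.5 and 96.0%. The 6375 that were not found there were overlapped by male cycle 13 H4K16ac in 47.1% and by male cycle 13 MSL3 in 61.6%, against 6.31 and 15.9% for shifted positions.

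The X to autosome density ratio of CLAMP in females was 1.61 at cycle 11 (95% block bootstrap 1.36 to 1.87, adjusted permutation p = 0.00025), 1.73 at cycle 12 (1.41 to 2.09, p = 0.000571) and 1.70 at cycle 13 (1.44 to 1.96, p = 0.0002). It was 1.60 at cycle 14 (1.25 to 2.00, adjusted permutation p = 0.00991) and 1.22 at 2-4 h (1.08 to 1.37, p = 0.0284). In males it was 0.649, 0.952, 1.22, 0.934 and 1.07, with adjusted permutation p of 0.208, 0.790, 0.0773, 0.582 and 0.532. On the log2 scale male minus female was −1.31 at cycle 11 (−2.25 to −0.61), −0.86 at cycle 12, −0.47 at cycle 13, −0.77 at cycle 14 and −0.20 at 2-4 h (−0.24 to −0.16). Each passed (adjusted permutation p = 0.00369 at cycle 11, 0.000338 at cycle 14 and 1.43e-05 at the others, from the smallest p the permutations can give). Over stages the mean was −0.72 (SD 0.42, n = 5). Male was lower at 5 of 5 stages, with an exact sign-flip p of 0.0625, the smallest that 5 stages allow (adjusted p = 0.125). The female 2-4 h ratio did not pass among the 300 strongest regions (1.39) or in blocks with at least 50 genes (1.11), and the male cycle 13 ratio passed among regions with −log10 q of at least 5 (1.29).

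The fourth comparison asked where H4K16ac differs between the sexes. At 2-4 h the longest X genes with at least 50% of the body covered in males and under 10% in females were FucT6, a fucosyltransferase gene (X 11706575 to 11709951, 71.3% against 9.83%), CG32537 (86.4% against 8.56%), CG6927 (90.4%), CG15773 (73.2%), CG15767 (54.5%), CG7860 (75.7%), CG12507 (68.2%) and CG15892 (66.3%), the last 6 with 0% in females. The other way, brk, the repressor of Dpp target genes (X 7307939 to 7311132), was covered over 59.9% in females and 0% in males, as were CG14229 (100%), CG14427 (74.1%) and Reepl1 (100%). By this measure 17 X genes were higher in males and 9 in females at 2-4 h, with 0.774% of X genes and 0.816% of autosomal ones higher in males. At cycle 14 the counts on X were 60 and 0, with 2.73% of X genes and 1.37% of autosomal ones higher in males. At cycle 13 they were 23 and 80. Higher in females were 3.64% of X genes and 4.25% of autosomal ones, and higher in males 1.05 and 0.816%, so the female excess there was not particular to X. At cycle 12 they were 1 and 12, with 0.546% of X genes and 0.266% of autosomal ones higher in females and 0.0455 and 0.155% higher in males. At cycle 11 the counts were 0 and 896, the latter 40.8% of the protein-coding genes on X beside 5.03% of those on the autosome arms. Mean body cover at female cycle 11 was 41.0% for X genes and 11.7% for autosomal ones, and at male cycle 14 it was 47.2 and 23.4%. At male cycle 11, where the list has 1201 regions, it was 0.762 and 1.67%, so hardly any gene could be called higher in males at that stage.

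In females the X to autosome ratio of H4K16ac regions was 2.34 at cycle 11 (95% block bootstrap 1.95 to 2.78, adjusted permutation p = 6.25e-05), 1.24 at cycle 12 (p = 0.0760), 1.25 at cycle 13 (p = 0.0622), 1.41 at cycle 14 (p = 0.00536) and 1.01 at 2-4 h (p = 0.886). In males it was 0.641 at cycle 11 (0.492 to 0.807, adjusted permutation p = 0.0061), 0.893 at cycle 12 (p = 0.371), 1.33 at cycle 13 (p = 0.0322), 0.944 at cycle 14 (p = 0.627) and 0.885 at 2-4 h (p = 0.208). Male minus female log2 was −1.87 at cycle 11, −0.48 at cycle 12, 0.08 at cycle 13, −0.58 at cycle 14 and −0.19 at 2-4 h, with adjusted permutation p of 1.43e-05 except at cycle 13 (0.352). The mean over stages was −0.61 (SD 0.75, n = 5), male was lower at 4 of 5 stages, and the exact sign-flip p was 0.125. In base pairs the mean was −0.70 (SD 1.44), male was lower at 2 of 5 stages, and the exact sign-flip p was 0.5. Female regions overlapped 89.8, 88.1, 51.6, 65.8 and 83.2% of male H4K16ac regions in stage order, each above shifted positions (adjusted permutation p = 0.000999).

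Direction on X depended on how H4K16ac was counted. In base pairs the male cycle 14 ratio was 2.36 and male minus female was 0.08 at cycle 14 and 0.03 at 2-4 h, both not past the threshold, while at cycle 13 it was 0.31 and passed (adjusted permutation p = 0.00563). Among regions with −log10 q of at least 5 the female cycle 11 ratio was 0.355, male minus female was 1.78 at that stage and the mean over stages was 0.25. The female cycle 14 ratio turned to 0.855 with that filter and to 0.320 among the 300 strongest regions. The male cycle 13 ratio no longer passed in either (1.10 and 1.07) or in blocks with at least 50 genes (1.17).

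The fifth comparison asked in which earlier lists the sites of 2-4 h embryos are found. The 2-4 h label gives an age and no nuclear cycle or embryo number, so these embryos may include some in cycle 14. Read depth and the amount of chromatin per pool were unknown, so a site absent from an early list may still have been bound. Regions of the female 2-4 h CLAMP list were overlapped by earlier female lists in 44.9% at cycle 11 (exact 95% interval 44.0 to 45.9), 15.3% at cycle 12, 32.5% at cycle 13 and 4.68% at cycle 14. Male regions were overlapped in 0.983, 5.40, 40.8 and 18.5%. On X, 58.7% of female and 49.6% of male regions were overlapped by any earlier list, beside 46.0 and 42.8% on the autosome arms. For H4K16ac the values were 49.4, 49.0, 60.3 and 60.0% in females and 11.5, 45.5, 45.7 and 70.9% in males. MSL3 on X gave 2.86, 6.79, 81.8 and 88.9%, and on the autosome arms 0.556, 0, 35.6 and 11.1%. From one stage to the next, the list before overlapped 87.6, 38.5, 86.6 and 4.68% of female CLAMP regions, 15.9, 11.7, 19.8 and 18.5% of male CLAMP regions. It overlapped 54.8, 0.192, 80.9 and 58.5% of male MSL3 regions on the arms. For H4K16ac this was 78.8, 64.3, 72.7 and 60.0% in females and 21.8, 40.7, 49.6 and 70.9% in males. Each overlap of one stage by the list of the stage before exceeded shifted positions (adjusted permutation p = 0.000999). The earlier CLAMP lists differed in length, from 529 regions in females at cycle 14 and 133 in males at cycle 11 to 8393 in males at cycle 14. Of the regions on the arms in the last, 23.9% were found at male 2-4 h. The earlier MSL3 lists ran from 33 regions at cycle 12 and 40 at cycle 11 to 15149 at cycle 13. Among regions with −log10 q of at least 5, H4K16ac at cycle 11 gave 10.6% in females and 0.934% in males, and MSL3 on X gave 34.5% at cycle 13.

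**Figure D3:**
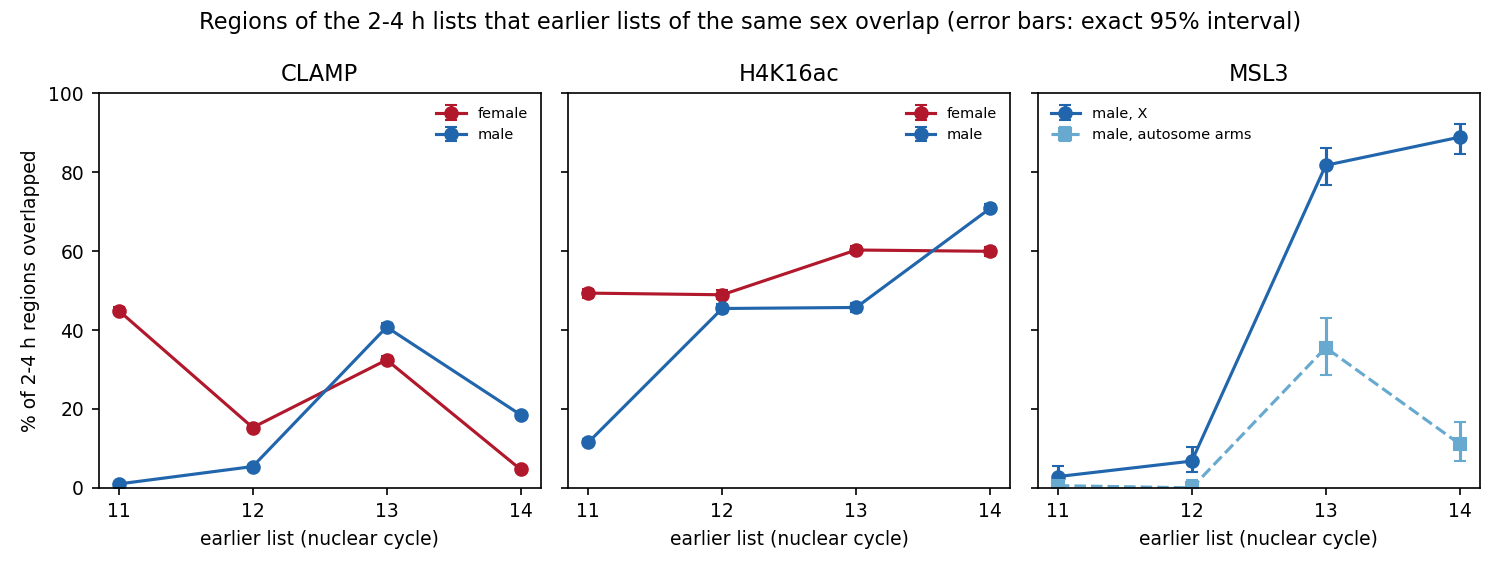
Percent of the regions of each 2-4 h list that are overlapped by the list of an earlier nuclear cycle of the same sex, with exact 95% intervals as error bars, for CLAMP, H4K16ac and MSL3. MSL3 regions on X are overlapped in 81.8% at cycle 13 and 88.9% at cycle 14, and male CLAMP regions in 40.8% at cycle 13 and 18.5% at cycle 14.

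The sixth comparison followed the roX genes, whose noncoding RNAs are parts of the MSL complex, and the genes of its proteins. At roX1 (X 3857230 to 3862697) CLAMP was found in 5 of 5 female lists, with fold between 5.44 and 11.8, and in 3 of 5 male lists, at cycles 13 and 14 and at 2-4 h. At roX2 (X 11579065 to 11580432) it was found in 5 of 5 female lists and in 4 of 5 male lists, from cycle 11 on (fold 4.71, X 11580155 to 11580378) and not at cycle 14. MSL3 was found within 1 kb of both genes in 3 of 5 lists, those of cycle 13, cycle 14 and 2-4 h. The cycle 13 list had MSL3 within 1 kb of 71.9% of protein-coding genes on X and 76.7% on the autosome arms. At roX2 its regions lay beside the gene and covered 0% of the body. At cycle 14 it covered X 11573769 to 11585008 around roX2 (fold 3.66), and at roX1 a region from X 3860968 to 3861189 (2.5). H4K16ac was found at both genes in 5 of 5 lists of each sex. With −log10 q of at least 5, it was found at roX1 in 3 female and 4 male lists and at roX2 in 2 female and 3 male lists, and MSL3 was found at roX1 in 1 list. In males the body of roX2 itself was overlapped in 3 H4K16ac lists.

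Among the protein-coding genes, CLAMP was found at Clamp itself (2L 22165720 to 22169143) in 5 of 5 female and 4 of 5 male lists. It was found at msl-2, the subunit made in males only, in 3 female and 2 male lists, at msl-3 and the helicase gene mle also in 3 and 2, and at msl-1 and the acetyltransferase gene mof in 2 lists of each sex. MSL3 was found at Clamp in 4 of 5 lists and at X-linked mof in 3. In the histone gene cluster (2L 21416953 to 21541681, 111 histone genes in tandem repeats) CLAMP regions were listed at 2-4 h only, 2 in females and 4 in males, and the strongest of them had the highest fold of its list (30.5 and 40.5). No H4K16ac or MSL3 list had a region there, and reads that map to many copies leave these values uncertain.

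**Figure D4:**
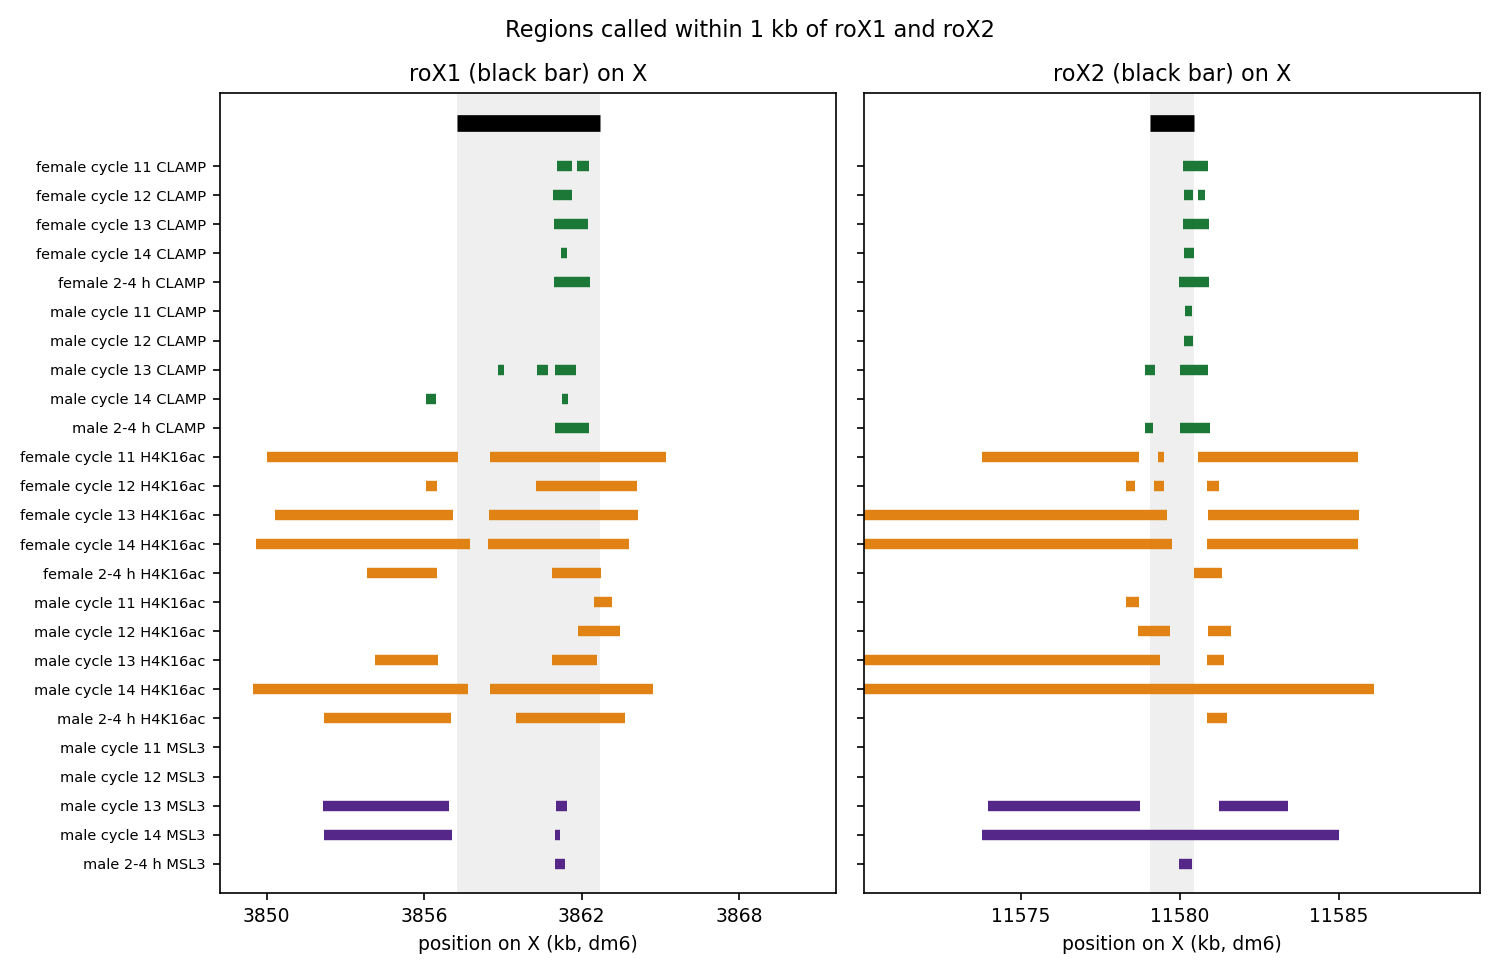
Regions of all 25 lists within 1 kb of roX1 and roX2 (black bars, gene extent shaded) against position on X in kb (dm6), green for CLAMP, orange for H4K16ac and purple for MSL3. At roX2, H4K16ac regions of cycles 13 and 14 in both sexes run past the left edge of the frame. CLAMP is present at roX2 in male lists from cycle 11, except at cycle 14. MSL3 regions lie beside roX2 at cycle 13 and over it at cycle 14 and 2-4 h.

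The last comparison counted the fixed gene lists with CLAMP within 1 kb, beside random lists of matched gene length. In females at cycle 12, CLAMP was found at 13 of 14 dorsoventral genes, among them the mesoderm regulator twi (fold 16.4), tup (9.86), Doc2 (7.11) and dpp (7.03). It was found at 9 of 9 pair-rule genes, among them run (16.4), opa (15.2), ftz (10.7) and slp1 (10.5). It was found at 9 of 10 gap genes, among them oc (24.5), btd (19.2) and ems (8.44). It was also found at 7 of 8 Hox genes, led by Abd-B (19.9), abd-A (15.5), Ubx (11.0) and Antp (7.74). First-wave zygotic genes had it in 11 of 13, including E(spl)m4-BFM (13.1) and slam (8.38). Sex determination genes had it in 9 of 16, including upd1 (10.6), sc (7.63) and Sxl (6.67), the switch gene for female identity. All 5 pioneer and GA-binding factor genes had it, led by psq (13.7), lola (11.6) and zld (10.5), and 4 of 8 MSL complex and roX genes. The percentile among 10000 random lists was at least 99.69 for each of these 8 lists. Ribosomal protein genes had it in 20 of 86 (percentile 100), led by RpL14 (8.72) and RpL30 (6.88). X-linked metabolic and housekeeping genes had it in 5 of 13, beside 16.9% of all protein-coding X genes, led by Act5C (11.2), and autosomal housekeeping genes in 4 of 10 (99.65), led by eIF4A (7.12).

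In males at cycle 12 CLAMP was found at 6 dorsoventral, 8 pair-rule, 9 gap, 5 Hox and 7 first-wave genes. Leading were twi (12.2), opa (11.6), oc (17.6) and Abd-B (12.1). It was found at 1 of 86 ribosomal protein genes (percentile 42.2) and at 1 of 8 MSL complex and roX genes (85.7). For the last list the male percentile was 99.91 at cycle 11, 99.93 at cycle 13 and 97.58 at 2-4 h. At 2-4 h it was found at all members of the dorsoventral, pair-rule, gap, Hox and sex determination lists in both sexes and at 84 of 86 ribosomal protein genes. The percentile was at least 98.8 for these lists except Hox (85.9 in females and 87.7 in males). In the male cycle 14 list, of whose regions 23.9% were found at 2-4 h, first-wave genes had CLAMP in 3 of 13 (57.1). Ribosomal protein genes had it in 19 of 86 (69.8) and MSL complex and roX genes in 3 of 8 (63.8). In that list pair-rule genes had it in 9 of 9 (100), gap genes in 9 of 10 (99.98), dorsoventral genes in 11 of 14 (99.41), autosomal housekeeping genes in 7 of 10 (99.69) and late differentiation genes in 9 of 12 (95.43). At female cycle 12, late differentiation genes had it in 3 of 12 (60.2), germline and follicle genes in 2 of 10 (86.1) and the histone locus body genes mxc and Slbp in neither (39.2), which lay nearer to random. Both of the last had it at female cycle 11 (95.33), at male cycle 13 (96.22) and at 2-4 h (82.2 in females and 82.6 in males). Replication-dependent histone genes had it in 0 of 111 at female cycle 12 and in 10 at male 2-4 h, and as copies at 1 locus they cannot be set against random lists.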

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

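The 3 patterns weighed here were picked after the results were seen, and only the tests of enrichment and of −log10 q at shared regions and of an X-wide shift were set down before their own result, that of −log10 q after the enrichment result was known; the tests of list length, a wrong label, a deeper library, the end of X, chance and older embryos were chosen after their results were seen.

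The density of CLAMP on X relative to the autosomes differed between the sexes by the block permutation test at each stage, with male minus female log2 of −1.31 at cycle 11, −0.86 at cycle 12, −0.47 at cycle 13, −0.77 at cycle 14 and −0.20 at 2-4 h. At the 3 stages with a male list as long as the female one or longer, the smallest difference was −0.20 (−0.24 to −0.16), at 2-4 h. The lists there had 10276 male and 10265 female regions on the arms, so shorter male lists are argued against at that stage only. At cycles 13 and 14 the male list was longer, and the male cycle 14 list stands apart from the others. Greater length may itself go with a lower ratio, since the longest female list had the lowest female ratio (1.22). At cycles 11 and 12 list length stays open. For the lower X dose of males as a brake on enrichment, fold on X relative to autosomes at shared regions was compared. Its male minus female log2 had a mean of −0.15 over stages (lowest stage −0.30, highest 0.08), above the bound of −0.5 set for it. This cannot decide the question, because the control is unknown and one with the same X dose would cancel such an effect. Regions lost in males do not enter that mean either. Fewer X reads in males may also lower detection on X. At shared regions −log10 q on X relative to autosomes was lower in males at each stage, by a mean of −0.44 (lowest stage −0.69, highest −0.04). Dose goes with sex in this design, so the test leaves fewer X reads open, and they cannot be told apart from a difference in binding. A difference between the sexes in CLAMP binding stays open as untested.

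H4K16ac also differed between the sexes by the same test, with male minus female log2 of −1.87 at cycle 11, −0.48 at cycle 12, −0.58 at cycle 14 and −0.19 at 2-4 h. At cycle 13 it was 0.08 and did not pass (adjusted permutation p = 0.352). In base pairs covered it was 0.31 at cycle 13 and passed (adjusted permutation p = 0.00563). The direction turned in base pairs covered at cycle 14 (0.083) and 2-4 h (0.030), and with −log10 q of at least 5 at cycle 11 (1.78).

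At cycle 11 the female ratio (2.34) lay above 1 and the male one (0.641) below it. MSL-2 is made in males only, but the mark was not limited to males or to X. Female lists held between 3698 and 6375 H4K16ac regions on the autosome arms. The female cycle 11 list covered 76.3% of the base pairs of X regions that had MSL3 in males at cycle 14. Older male embryos as the whole sample are argued against by 2 sets of age markers: the percent of late differentiation and Hox genes with H4K16ac minus that of first-wave genes was −69.6 in this list, −79.6 at male cycle 11 and 49.2 at male cycle 14, a difference from the last of −119 (−152 to −83.5, permutation p = 9.999e-05 against random lists), or −75.4 (−111 to −39.6) in gene bodies alone. A deeper library may contribute and stays open, since autosomal base pairs covered were 0.787 times those of female cycle 12 (0.764 to 0.809) but autosomal regions were 1.07 times as many. An X-wide shift, such as a control library with another X dose, stays open too. It was tested on protein-coding genes whose body had H4K16ac at female cycle 12, without a measure of expression. Those on X without MSL3 at male cycle 14 had 1.73 times the body cover of the autosomal ones (1.43 to 2.00, around the bound of 1.5 set for it). Those on X with MSL3 had 2.89 times. The autosomal genes were taken with or without MSL3. A swap of the 2 cycle 11 H4K16ac labels, which would turn the sign of the difference, a female state of this stage, and some male embryos among the females were not tested, and chromosome Y held 5 regions in both cycle 11 lists.

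The male cycle 12 MSL3 list had 30 of its 31 regions on the arms on X. The repeat-rich end of the arm may account for those beyond 22 Mb, of which the cycle 11 list held 16 of 17, while the other 13 lie before 22 Mb, outside that end. Chance calls are argued against for these 13, since the cycle 14 list overlapped 13 of them against 1.62 for shifted positions (permutation p = 0.000999, the smallest 1000 shifts can give). A few older embryos in the pool stay open, since the median rank of these sites by fold at cycle 14 was 19 of 590, and early binding at the strongest sites predicts the same, so these cannot be told apart. None of the 33 regions reached a −log10 q of 5.

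Mitochondrial regions, which no comparison used, passed the 3 counts that a count of 0 allows in the female cycle 14 CLAMP list (5), the female 2-4 h CLAMP list (8), the male cycle 12 CLAMP list (4), the male 2-4 h CLAMP list (8) and the female cycle 11 H4K16ac list (4).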

How the results depend on the processing

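Leaving out X beyond 22 Mb, blocks with at least 50 genes, every summit, gene bodies alone and the leaving out of single lists were chosen after the data were seen; the other alternatives were planned. Of 596 alternative values for 176 results, 426 kept their direction and their side of the threshold or stayed within their interval, 105 moved, 30 reversed, 20 newly passed and 15 no longer passed. Counting every summit left all 15 of its values as they were. Except where stated, the cause was not tested. No paired analysis was possible because replicate numbers pair no lists, each group having 1; the sexes are paired only by stage, in the sign-flip test. The GA motif alternatives and 500 bp around gene starts were not run, for want of a genome sequence and of strand. Lists under 300 regions gave no value among the 300 strongest, nor did male cycle 12 MSL3 at −log10 q of at least 5, where it has 0 regions. Depth was unknown, so what it limits was not measured.

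With −log10 q of at least 5, the X to autosome ratio of H4K16ac reversed in females at cycle 11 (0.355), 12 (0.936) and 14 (0.855) and in males at cycle 11 (1.22), no longer passed in males at cycle 13 (1.10) and newly passed in males at cycle 14 (0.734). That of male CLAMP newly passed at cycle 13 (1.29), and that of MSL3 at cycle 13 reversed (2.85, share on X 38.1%). Male minus female log2 for H4K16ac reversed at cycle 11 (1.78) and in its mean over stages (0.25). The overlap of MSL3 by CLAMP at cycle 13 turned above shifted positions on X (14.5%) and no longer passed on the autosome arms (5.19%), nor at cycle 14 on X (29.3%) or the autosome arms (50%), where fewer regions are tested.

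Under the same filter, the shares of 2-4 h regions present at cycles 11, 12, 13 and 14 were 42.9, 13.6, 29.5 and 4.03% for female CLAMP, 10.6, 43.0, 65.8 and 49.1% for female H4K16ac and 0.934, 39.0, 23.8 and 69.2% for male H4K16ac; for male CLAMP they were 38.3% at cycle 13 and 16.7% at cycle 14. For MSL3 on X they were 24.1, 34.5 and 62.1% at cycles 11, 13 and 14, and on the autosome arms 0, 0 and 0%.

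Among the 300 strongest regions, ratios of H4K16ac reversed in females at all stages (0.285, 0.483, 0.999, 0.320 and 0.391). In males they no longer passed at cycle 11 (0.718) and 13 (1.07) and newly passed at cycle 12 (0.373), 14 (0.151) and 2-4 h (0.217). Male minus female reversed at cycle 11 (1.33). CLAMP at 2-4 h no longer passed in females (1.39) and reversed in males (0.999), and MSL3 at cycle 13 reversed (2.32, share on X 33.3%).

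With base pairs covered in place of regions, H4K16ac newly passed in females at cycle 13 (1.36) and reversed in males at cycle 14 (2.36) and 2-4 h (1.10). Male minus female log2 of base pairs covered newly passed at cycle 13 (0.31) and reversed at cycle 14 (0.083) and 2-4 h (0.030). By construction this comes from region width, and at cycle 14 the male median was 1174 bp on X and 810 bp on the autosome arms. MSL3 no longer passed at cycle 12 (340, share on X 98.7%) and 13 (0.839, 15.4%). With regions within 1 kb merged, the ratio newly passed for male CLAMP at cycle 13 (1.25) and male H4K16ac at cycle 14 (0.786) and no longer passed for female H4K16ac at cycle 14 (1.19). Chromosome 4 among the autosomes turned female 2-4 h H4K16ac to 0.9998.

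Blocks of 250 kb changed no value, and male CLAMP at cycle 13 (1.22), female H4K16ac at cycles 12 (1.24) and 13 (1.25) and MSL3 at cycle 11 (4.62) newly passed. Without X beyond 22 Mb, the same first 3 newly passed (1.29, 1.28 and 1.29), and MSL3 at cycle 11 reversed (0.380, share on X 5%), since 18 of its 19 X regions lie there. In blocks with at least 50 genes, CLAMP no longer passed in females at 2-4 h (1.11), newly passed below 1 in males at cycle 14 (0.824) and reversed in males at 2-4 h (0.961). H4K16ac reversed in females at 2-4 h (0.929), newly passed in males at cycle 12 (0.786), 14 (0.835) and 2-4 h (0.807) and no longer passed at cycle 13 (1.17); MSL3 at cycle 11 reversed (0.546).

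With 50% of a region to be covered, the overlap of MSL3 by CLAMP on X fell to 0% at cycle 12 and to 1.5% at cycle 13, now relative to shifted positions in the other direction, and that by H4K16ac at cycle 12 no longer passed (10%). Shares of 2-4 h regions present fell by construction, to 28.2, 6.27, 17.5 and 0.964% for female CLAMP at cycles 11 to 14, 0.331, 2.13, 29.9 and 9.16% for male CLAMP, 31.6, 36.8, 47.8 and 42.9% for female H4K16ac and 2.45, 28.8, 22 and 53.9% for male H4K16ac. For MSL3 at cycle 13 they were 65.7% on X and 25.6% on the autosome arms.

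Leaving out each stage in turn, the mean male minus female log2 ranged from −0.86 to −0.58 for CLAMP and from −0.78 to −0.29 for H4K16ac. The value of −0.29 was that without cycle 11. Without the female cycle 11 H4K16ac list, 13 combinations of gene list and stage lay at or above percentile 95 for female H4K16ac, against 20 with it, as fewer combinations were counted; 1 of the 20 is the X-linked list, whose percentile reflects its chromosome.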

Other observations

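The gene lists were fixed before the data were seen, and only gene bodies without flanks and the tests on the male cycle 14 CLAMP list and on the 13 early MSL3 regions were chosen after the result was seen. Ribosomal protein genes had H4K16ac within 1 kb in 81 of 86 at female cycle 11 (percentile 100 of random lists matched on length), led by RpL11 (fold 4.17) and RpL30 (4.14). The count was 22 of 86 at male cycle 11 and 83 of 86 at male 2-4 h, led by RpS15 (3.74), and with −log10 q of at least 5 it was 20 at female cycle 11 (percentile 100) and 0 at male cycle 11. First-wave zygotic genes had it in 11 of 13 at cycle 11 in both sexes (99.88 in females, 100 in males), with bnk (3.60 in females and 5.09 in males) and slam (3.32 and 4.61) among them. In gene bodies alone the count was 5 in females (57.4) and 4 in males (99.58), and with −log10 q of at least 5 it was 4 (99.67) and 2 (99.94). At cycle 14 it was found at 3 of them in females and 4 in males, where Sry-alpha (3.58) and tld (3.84) were among the male ones. Hox genes had it in 0 of 8 at cycle 11 (0.075 in females and 13.0 in males) and in 7 of 8 at 2-4 h (74.0 and 73.5, near random), or 5 of 8 with −log10 q of at least 5, led in males by lab (2.24) and Abd-B (2.04). Gap genes had it in 3 of 10 at male cycle 14 (0.495) and pair-rule genes in 2 of 9 (0.230), below most random lists, with hb (2.25) and opa (2.23) among them; in the male cycle 13 list they had it in 7 and 8. The female cycle 11 list held the mark at 14 of 16 sex determination genes (99.4). Of the 16, 5 are on X, and this list had the mark at 72.1% of protein-coding X genes and 49.9% of autosomal ones. Among those with it was sisA (3.16), an X-linked gene that activates Sxl, over 100% of its body. The male cycle 11 list had a region beside that gene (4.46).

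MSL3 at cycle 14 was found at 7 of 8 MSL complex and roX genes (percentile 99.98), including roX2 (3.66), mof (3.17) and Clamp on 2L (2.18). Of these 8 genes 3 are on X, so the percentile partly reflects chromosome. MSL3 was at 50.6% of protein-coding X genes and 9.56% of autosomal ones. It was also found at 6 of 13 X-linked metabolic and housekeeping genes, led by SkpA (3.73), arm (3.06), RpL22 (2.99) and Act5C (2.56). It was found at 12 of 86 ribosomal protein genes (74.4), and the 4 of highest fold were the X-linked RpS19a (4.22), RpL7A (4.20), RpL35 (3.8) and RpS5a (3.56). With −log10 q of at least 5 the MSL complex and roX genes had it in 2 of 8 (91.75) and ribosomal protein genes in 8 of 86 (96.86). No gap, pair-rule or dorsoventral gene had it at that stage. At 2-4 h the autosomal site of MSL3 at Clamp remained in the list (4.49), and RpS21 (3.88) and RpL38 (3.63) on 2L and 2R were among 6 ribosomal protein genes with it, none of them with −log10 q of at least 5.

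The male cycle 14 CLAMP list stood apart from the others, and 2 tests of it are given here as values with no explanation. Of its 500 strongest regions, 58.2% were found at male 2-4 h, against at least 93.8% for the other CLAMP lists with 500 regions or more. Its 6375 regions not found there were overlapped in 47.1% by male cycle 13 H4K16ac, in 61.6% by male cycle 13 MSL3 and in 21.8% by male cycle 14 H4K16ac, where shifted positions gave 6.31, 15.9 and 11.0%. Chromosome 4 held 7 regions of that list, 9 of male cycle 13 H4K16ac and 15 of male cycle 13 MSL3, beside 61 of male cycle 13 CLAMP and 142 of male cycle 14 H4K16ac.

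The 13 regions of male cycle 12 MSL3 before 22 Mb lay over genes of varied function, of which anox, ebo, Stt3A, the catalytic subunit of an oligosaccharyltransferase, tay and Pgant7 complete the list beside the 8 of higher fold. Female cycle 11 H4K16ac overlapped 12 of these 13, and female H4K16ac at cycles 12, 13, 14 and 2-4 h overlapped 2, 4, 13 and 4. Male H4K16ac in stage order overlapped 0, 0, 6, 13 and 13. Of all 568 X regions of the cycle 14 MSL3 list to 22 Mb, female H4K16ac in stage order overlapped 547, 370, 447, 509 and 409. Male H4K16ac overlapped 44, 281, 427, 557 and 481 of them. The high counts among the 13 are therefore not particular to these early sites. Cycle 14 regions on X are wider (median 3049 bp), so the 2 sets are not matched.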
